A study of Mus musculus with 16 samples.

How the data were processed

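Mice of the C57BL/6J strain were immunized in the abdomen with 100 µg of NP-KLH in 50% alum with 1 µg of lipopolysaccharide, per the labels. Cells of the CD138+ samples were enriched with magnetic beads against CD138, and in the sorted libraries they were then sorted as CD138+CD44+CD11a+ cells by their B220 level, per the labels' protocols. The libraries were made with droplet-based 5′ chemistry with molecular identifiers (UMIs), with a later version of the kit in experiment 5, per the labels. The deposited files hold UMI counts per gene and cell barcode, made with Cell Ranger 3.1.0 on the mm10 assembly, per the submitters' processing notes. The matrices were already filtered to barcodes called as cells. Whether doublets were removed before deposit, and which gene annotation was used, are not given in the sources used here. Each of the 7 matrices lists the same 28692 genes, and gene positions were taken by gene identifier from the GENCODE annotation of the same assembly. The 8 receptor libraries and the day 35 CD138+ spleen library of experiment 1 were not analysed here.

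The files held between 7167 and 16806 barcodes per library. Cells with at least 200 detected genes and at most 10% mitochondrial UMIs were kept. Doublets were predicted in each library with an implementation, written for this work, of the scrublet method (simulated doublets and a nearest-neighbour score), with an expected share proportional to the number of cells (5.27% to 13.2%). The score threshold was the minimum between the simulated peaks where there was one, and otherwise the expected share. Between 3.29% (experiment 4 marrow) and 5.96% of cells per library were called and removed. In experiment 5 spleen 3.7% were called where 13.2% were expected, so doublets may remain there. Median UMIs per kept cell ranged from 3817 in the day 21 library to 14370 in the B220-negative library, and were 11304 and 6521 in spleen and marrow of experiment 4 and 8455 and 11878 in experiment 5. UMIs outside the immunoglobulin genes had medians from 4849 to 7370 in plasma cell-like cells of the CD138+ libraries. Intervals and floors cover counting error only.

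Cells were clustered without the 392 immunoglobulin genes with scanpy 1.11.5, using 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method (leidenalg 0.10.2) at a resolution of 1 with seed 1. Of 37 clusters, 10 were named plasma cell-like from marker lists of 16 cell classes. A name required at least 3 detected markers and leading genes that did not go against it. No cluster was named marginal zone or B-1, memory B, NK, conventional dendritic, megakaryocyte or stromal. Clusters 6 and 10 of the plasma cell-like clusters had median UMIs at 0.21 and 0.305 of their samples' medians but had plasma cell markers among their top 10 genes, and they were left out in an alternative chosen after the data were seen. Clusters 8 and 35 were led by cell cycle genes, and the stress gene Fosb was among the leading genes of clusters 10 and 35.

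The isotype of a plasma cell-like cell was called when 1 class held at least 80% of at least 10 heavy chain constant region UMIs, and between 1.07% and 8.32% of these cells per library had no call. A cell was called cycling with a UMI for at least 4 of 20 cell cycle genes and non-cycling with at most 1. For shares at equal depth each cell was thinned to 2000 UMIs outside the immunoglobulin genes, and shallower cells were left out. Shares have exact Clopper-Pearson intervals at 95%, and a share of 0 has a floor of 3 counts.

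Cells are not replicates, so UMI counts were summed per library over plasma cell-like cells, and per isotype or cycling class where at least 50 cells were present. Immunoglobulin genes other than Jchain were left out of the sums and of the library size. Sums were tested with edgeR 4.0.16 (filterByExpr, TMM, glmQLFit and glmQLFTest with robust spread) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The test of marrow against spleen used the 2 libraries per tissue of experiments 4 and 5 with experiment as a term, because the labels tie the gate and the chemistry to the experiment number. Differences of experiment 5 from experiment 4 in spleen and in marrow correlated over 10021 genes (r = 0.594), and genes are not independent replicates. IgM, IgG and IgA sums of the 6 CD138+ libraries entered 1 fit with library as a term, and cycling and non-cycling sums another. Interactions with tissue were tested in the same designs. Because the fit of marrow against spleen had 1 residual degree of freedom, its spread was moderated over all genes.

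The 17 gene lists covered the cell cycle, DNA replication, folding and the unfolded-protein response, translocation into the endoplasmic reticulum, plasma cell identity, B cell identity and antigen presentation, homing and adhesion, survival and apoptosis, inhibitory and regulatory receptors, interferon response, oxidative phosphorylation, glycolysis, amino acid supply and the ATF4 response, immediate-early and stress genes, NF-κB, isotype regulators and the proteasome. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry, which tests whether a list's genes move one way and does not compare them with other genes. Lists, markers, the tests between groups, most alternatives and the rule for named genes were fixed before the data were examined. Binomial thinning of sums replaced another thinning method after its first values were seen. The alternatives without low-UMI clusters or neutrophil genes and some tests of explanations were also chosen after the data were seen. Which lists are described with example genes was chosen after the list results were seen. Named genes were the 8 largest changes in each direction with adjusted p under 0.05, an average log2 CPM of at least 4 and the same direction in each experiment or library, and up to 4 genes of smallest p from each described list. Tigit, Prdm1, Sdc1, Cxcr4, Tnfrsf17, Mki67, Ptprc and Cd74 were always included. The first part of this rule left out immunoglobulin, T cell receptor, mitochondrial and ribosomal protein genes, genes named only by a clone or model number, Xist, Tsix and Y-linked genes, and the defining genes of the cycling contrast. The text gives a selection of the genes the rule took. Some genes the rule took are not reported here.

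The day 14, day 21 and B220-negative libraries had 1 library each. Their values are CPM outside the immunoglobulin genes with exact Poisson intervals at 95%, and the genes named were the 5 largest folds each way with at least 100 UMIs in 1 of the 2 libraries and a mean of at least 50 CPM, together with the genes always included. Gene list medians were placed among 10000 random lists of equal size matched on mean expression.

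Each test was run first on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. Apart from these, each gene had the same mean in all libraries, so no differences between experiments or libraries were simulated. The spread came from the same fits, so the simulation cannot show whether that spread is right. For marrow against spleen 73 and 95 were recovered and 16 unchanged genes were called, for experiment 5 against 4 the numbers were 62, 95 and 17, for IgG 91, 99 and 12, for IgA 85, 98 and 8, and for cycling 91, 100 and 16. For the interactions with tissue they were 52, 84 and 13 (IgG), 35, 84 and 10 (IgA) and 59, 84 and 14 (cycling).

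Alternatives covered DESeq2 1.42.0 as the test and its size factors in edgeR, no filter on low counts, immunoglobulin genes kept, cells with at least 500 genes and at most 5% mitochondrial UMIs, doublets kept, sums thinned at random (binomially) to the smallest one, other cluster resolutions (0.5 and 2), other limits for isotype (95%, or 50 UMIs) and cycling (6 of 20 genes), single isotypes, non-cycling cells, subsets of libraries, fits without the block and each library left out in turn. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.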

Results

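Antibody-secreting cells were profiled by droplet-based 5′ single-cell RNA sequencing after immunization of C57BL/6J mice with NP-KLH, a hapten coupled to a carrier protein, given with alum and lipopolysaccharide. The series holds 16 samples, of which 7 transcriptome libraries were analysed here. The other 9 samples, 8 of them B cell receptor libraries, were not analysed here. In 6 of the 7 libraries, cells were enriched for CD138, the surface proteoglycan encoded by Sdc1 that marks plasma cells. These were CD138+ spleen cells at day 21 (experiment 1), B220-negative CD138+ spleen cells at day 35 (experiment 3), and a spleen and a marrow library at day 35 from each of experiments 4 and 5. Experiment 4 held the B220-negative and B220-intermediate CD138+ sorts, and experiment 5 also included the B220+ sort and used a later version of the chemistry. The remaining library held NP-binding B220+ spleen cells at day 14 (experiment 2). Total UMI counts ranged from 50274267 in the day 21 library to 173820710 in the experiment 5 spleen library, and between 6246 and 15928 cells per library were kept. Immunoglobulin genes took 1.58% of UMIs in the day 14 library and 58.7% in the B220-negative library. The labels do not state that libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. In the fit that compared marrow with spleen and experiment 5 with 4, that spread was mostly pooled over genes.

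Plasma cell-like cells, named from clusters that expressed markers such as Jchain, Derl3 and Txndc5, made up 99.1% of the B220-negative library (8127 of 8197 cells). They made up 92.7% of the marrow library of experiment 5 (6399 cells), 70.1% of its spleen library (11170 cells) and 66.1% of the spleen library of experiment 4 (6129 cells). The day 21 library held 33.9% (2117 cells), beside 43.7% mature B cell-like and 7.14% germinal centre B cell-like cells. In the day 14 library 71.8% of cells were germinal centre B cell-like, 27.3% were mature B cell-like and 13 cells were plasma cell-like. The marrow library of experiment 4 stood apart, with 10.8% plasma cell-like cells (843 cells), 57.5% neutrophil-like and 16.3% monocyte or macrophage-like cells. Neutrophil-like cells were 17.0% of the experiment 4 spleen library and 1.09% of the experiment 5 marrow library. These shares follow the enrichment and sort gates as well as the tissue, and are not comparable as tissue composition. Clusters left without a name held between 0.439% of cells (B220-negative library) and 14.2% (experiment 4 marrow).

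Marrow plasma cell-like cells held larger shares of switched isotypes than spleen cells of the same experiment. IgA cells were 48.6% of plasma cell-like cells in marrow (95% exact binomial interval 45.2 to 52.1) and 25.1% in spleen (24.0 to 26.2) in experiment 4. In experiment 5 they were 11.5% (10.7 to 12.3) and 3.04% (2.73 to 3.37). IgG cells were 31.7% in marrow and 14.1% in spleen in experiment 4, and 12.1% and 10.5% in experiment 5. IgM cells, the largest class in 5 of the 6 CD138+ libraries, reached 86.1% in the B220-negative library and 18.6% in the experiment 4 marrow. Cells expressing at least 4 of 20 cell cycle genes were 10.6% and 11.3% of plasma cell-like cells in marrow and spleen of experiment 4, and 7.64% and 10.7% in experiment 5. With each cell thinned to 2000 UMIs outside the immunoglobulin genes, the experiment 4 difference in cycling share changed sign, from -0.716 to 0.165 percentage points. In the B220-negative library 1.05% of plasma cell-like cells were cycling. No test was made of these shares, because each tissue had 2 libraries, and the intervals cover counting error only. These shares, too, may follow the sort gates as well as the tissue. The mix of B220 sorts in a library could differ between tissues, which was not tested.

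The first comparison asked how plasma cell-like cells of marrow differed from those of spleen at day 35. Ccr10, a chemokine receptor that guides antibody-secreting cells to epithelial tissues, was 1.61 ± 0.14 higher in marrow on the log2 scale (SE, n = 2 libraries per tissue, adjusted p = 7.63e-26). Its mean was 221 ± 123 CPM in marrow and 83.6 ± 71.4 CPM in spleen (SD, n = 2), with log2 differences of 1.20 and 2.02 within experiments 4 and 5. The SE and p of this fit rest mostly on a spread pooled over genes, because it had 1 residual degree of freedom. They do not measure a single gene's own spread between the experiments. Ly6c2, a surface antigen carried by plasma cells, was 0.98 ± 0.12 higher (adjusted p = 3.74e-13), and Slpi, a secreted protease inhibitor, was 0.67 ± 0.11 higher (adjusted p = 1.21e-06). Apoe, the lipid carrier apolipoprotein E, was lower in marrow by log2 -2.02 ± 0.17 (adjusted p = 7.65e-29), and the scavenger receptor gene Cd36 by -2.00 ± 0.20 (adjusted p = 1.4e-20). Bcl2l11, which encodes the pro-apoptotic protein BIM, was lower by -0.93 ± 0.15 (adjusted p = 1.91e-07). Each of these 6 genes had the same direction in both experiments, which the rule for naming Ccr10, Apoe, Cd36 and Bcl2l11 required.

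Ccr10 (ENSMUSG00000044052) lies on chromosome 11 (101172997 to 101175443, minus strand), Ly6c2 (ENSMUSG00000022584) on chromosome 15 (75108158 to 75111970, minus strand), Apoe (ENSMUSG00000002985) on chromosome 7 (19696109 to 19699188, minus strand) and Cd36 (ENSMUSG00000002944) on chromosome 5 (17781690 to 17888801, minus strand). All 4 are annotated as protein coding on the mm10 assembly. Ly6c2 has a close paralog, Ly6c1, so the split of reads within that pair is uncertain. Tmem176a (log2 1.16) and Tmem176b (log2 1.24) overlap on opposite strands of chromosome 6, and the assignment of reads between them was not tested. Among IgA cells alone the calls of Ccr10 (0.61, adjusted p = 0.235), Ly6c2 (adjusted p = 0.652), Tmem176a (adjusted p = 0.867), Tmem176b (adjusted p = 0.693) and Cd36 (-0.08, adjusted p = 1) were lost, and Apoe stood at 0.04. Bcl2l11 was not called in IgG (adjusted p = 0.636) or IgA cells alone (adjusted p = 1). Among IgM cells alone Slpi (0.15, adjusted p = 0.891), Apoe (adjusted p = 0.962) and Cd36 (adjusted p = 0.732) did not pass. Slpi was not called in IgG cells alone (adjusted p = 0.558) or by DESeq2 (adjusted p = 1), and with immunoglobulin genes kept neither Slpi (adjusted p = 0.268) nor Apoe (adjusted p = 0.228) passed.

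Among gene groups, 5 of the 24 measured genes for B cell identity and antigen presentation fell in marrow and none rose, and 12 fell and 3 rose adjusted over the list alone. Pax5, the B lineage transcription factor, changed by -1.75 ± 0.49 (adjusted p = 0.0266; means of 0.448 CPM in marrow and 1.59 CPM in spleen). Cr2, a complement receptor of B cells, changed by -1.64 ± 0.40 (adjusted p = 0.00664; 1.14 and 2.65 CPM), and H2-DMb2, a class II peptide loading gene, by -0.81 ± 0.22 (adjusted p = 0.0187). The list test gave adjusted p = 8.11e-05, and adjusted p = 0.995 with an estimated correlation. Mature B cell-like cells were 17.2% of all cells in experiment 5 spleen and 0.550% in experiment 5 marrow, and 0.248% and 0.051% in those of experiment 4. Of 19 interferon-response genes, 2 fell (4 adjusted over the list alone). Ifi27l2a was lower by -0.94 ± 0.13 (adjusted p = 1.38e-09). The interferon list had adjusted p = 1.05e-04, and adjusted p = 0.995 with an estimated correlation. DESeq2 did not call Pax5, Cr2 (adjusted p = 1 for both) or H2-DMb2 (adjusted p = 0.662). With immunoglobulin genes kept Pax5 (adjusted p = 0.167), Cr2 (adjusted p = 0.37) and H2-DMb2 (adjusted p = 0.104) did not pass.

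Homing and adhesion genes went both ways in marrow, with 3 higher and 3 lower of 24 (5 and 7 adjusted over the list alone; list adjusted p = 0.601). Klf2, a regulator of lymphocyte trafficking, was 0.64 ± 0.16 higher (adjusted p = 0.00488; -0.56 in IgA cells alone). S1pr1, a receptor for exit into blood, was lower by -1.06 ± 0.26 (adjusted p = 0.00577), and DESeq2 called neither gene (adjusted p = 0.506 and 0.716), nor did edgeR with thinned sums (adjusted p = 0.235 and 0.335). Of 24 plasma cell genes, 2 rose and 22 did not pass the test, and 5 rose and 2 fell adjusted over the list alone (list adjusted p = 0.614). Prdm1, the regulator of plasma cell differentiation (log2 -0.27, adjusted p = 0.644), Sdc1 (0.16, adjusted p = 0.871) and Tnfrsf17, the survival receptor BCMA (0.38, adjusted p = 0.156), did not pass. Neither did Cxcr4, the receptor for the marrow chemokine Cxcl12 (-0.18, adjusted p = 0.923), the proliferation marker Mki67 (-0.27, adjusted p = 0.598), Ptprc (-0.32, adjusted p = 0.433) or Cd74 (0.24, adjusted p = 0.472). Tigit, an inhibitory receptor known from T and NK cells, was at 0.41 ± 0.14 (adjusted p = 0.126). It stood at -0.12 in IgM cells alone and at 0.97 in IgG cells alone (adjusted p = 0.00607).

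Ngp, a granule gene of neutrophils, was 2.81 ± 0.23 higher in marrow plasma cell-like cells (adjusted p = 4.78e-22), with a mean of 45.4 ± 62.3 CPM in marrow and 8.12 ± 11.4 CPM in spleen (SD, n = 2). Camp, another such gene, was 2.67 ± 0.30 higher (adjusted p = 2.14e-07), and the monocyte and granulocyte gene Lyz2 was 1.20 ± 0.21 higher (adjusted p = 9.14e-05). DESeq2 called none of the 3 (adjusted p = 0.406, 0.825 and 1), and neither did edgeR with immunoglobulin genes kept (adjusted p = 0.86, 0.936 and 0.958). Within experiment 4 the log2 differences were 2.46 for Ngp, 2.24 for Camp and 1.98 for Lyz2, and within experiment 5 they were 4.18, 4.33 and 0.43, from 1 library against 1. In experiment 5 marrow Ngp and Camp together had 88 UMIs in 6399 plasma cell-like cells, 21 of them in 1 cell, so these folds lie near the floor. With both the experiment 4 marrow library and the experiment term left out, Ngp was at -2.54, Camp at -2.42 and Lyz2 at 0.17, while the coefficient of experiment 5 against 4 for Ngp was -6.61. Neutrophil-like cells were 57.5% of all cells in experiment 4 marrow. The 261 genes high in neutrophil-like cells took 0.453% of UMIs outside the immunoglobulin genes in marrow and 0.345% in spleen in experiment 4, and 0.369% and 0.387% in experiment 5. With these 261 genes left out, 81 genes were higher and 68 lower in marrow.

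In all, 108 genes were higher and 71 lower in marrow among 12146 tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in a fit with experiment as a block, from sums of 6698244 to 69643400 UMIs per library. The test had 1 residual degree of freedom, so its spread was pooled over genes. Without the block edgeR called 0 genes in either direction, with 216 of 12146 at an unadjusted p under 0.05 and Ccr10 and Apoe at adjusted p = 1. DESeq2 with the block called 22 genes higher and 8 lower, all 30 of them among the 179. With 1 library left out and no experiment term, edgeR called 0 genes without the spleen library of experiment 4 or of experiment 5 (227 and 76 at an unadjusted p under 0.05). It called 3 genes without experiment 4 marrow and 1 without experiment 5 marrow. In these fits Slpi stood at -0.05 without experiment 4 marrow, and Apoe at -0.04, Pax5 at 0.72 and H2-DMb2 at 0.63 without experiment 5 spleen. No cluster held most plasma cell-like cells of any of the 4 libraries. A cluster led by Jchain, Ccr10 and Tigit was the largest in both libraries of experiment 4, with 46.1% in marrow and 24.7% in spleen. Other clusters were the largest in experiment 5, with 41.6% in marrow and 31.1% in spleen.

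The coefficient of experiment in the same fit compared the wider sort gate and later chemistry of experiment 5 with experiment 4, and gate, chemistry and animals cannot be told apart. H2-Aa, a chain of an antigen-presenting class II molecule, was 1.94 ± 0.13 higher in experiment 5 (adjusted p = 4.04e-43), at 607 ± 9.02 CPM against 160 ± 48.9 CPM (SD, n = 2). Fcmr, the Fc receptor for IgM, was 2.58 ± 0.16 higher (adjusted p = 2.13e-44; adjusted p = 0.105 with immunoglobulin genes kept). Of 24 genes for B cell identity and antigen presentation, 20 rose and none fell, with the same count adjusted over the list alone. In the list test this group had adjusted p = 1.29e-12, and adjusted p = 0.925 with an estimated correlation. Mature B cell-like cells were 17.2% of cells in experiment 5 spleen against 0.248% in experiment 4 spleen, and 0.550% against 0.051% in marrow. Ptprc, which encodes the B220 antigen used in the gates, was 0.57 ± 0.14 higher (adjusted p = 0.00121). Mki67 was 0.47 ± 0.14 higher (adjusted p = 0.00814) and Cd74, the class II invariant chain, 0.34 ± 0.11 higher (adjusted p = 0.0204), and DESeq2 called neither (adjusted p = 0.0638 and 0.193). Prdm1 (0.22, adjusted p = 0.368), Sdc1 (-0.28, adjusted p = 0.153), Cxcr4 (0.23, adjusted p = 0.457) and Tnfrsf17 (-0.09, adjusted p = 0.766) did not pass.

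Ccr9 and Ccr10, receptors for mucosal homing, were lower in experiment 5, Ccr9 by log2 -2.67 ± 0.19 (adjusted p = 1.72e-40) and Ccr10 by -1.61 ± 0.14 (adjusted p = 6.21e-27). Itgb7, the beta chain of the gut-homing integrin, was also lower (-1.51 ± 0.15, adjusted p = 6.62e-22), as was Tigit (-0.55 ± 0.14, adjusted p = 0.00123). The IgA share was lower in both tissues of experiment 5, as given above. Ngp was lower by -6.61 ± 0.25 (adjusted p = 3.62e-60), as was the neutrophil-like share of both tissues. Immediate-early and stress genes rose in 3 of 21 cases and fell in none (5 rose adjusted over the list alone), led by Fosb (1.77 ± 0.15, adjusted p = 1.9e-30). This list had adjusted p = 2.3e-04, and adjusted p = 0.925 with an estimated correlation. Amino acid supply and ATF4-response genes rose in 6 of 20 cases and fell in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.0338, and adjusted p = 0.925 with an estimated correlation). Of 12146 genes, edgeR called 781 higher and 730 lower in experiment 5. DESeq2 called 293 and 281, and a fit without the tissue term 272 and 233. In that fit Ccr10 (adjusted p = 0.629), Tigit (adjusted p = 0.176), Ptprc (adjusted p = 0.0635) and Ngp (adjusted p = 0.326) did not pass.

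IgG and IgM plasma cell-like cells were compared within each of the 6 CD138+ libraries. Slpi had the largest rise of the named genes in IgG cells, 3.45 ± 0.43 on the log2 scale (adjusted p = 1.69e-04), from 2598 ± 721 CPM in IgM cells to 29855 ± 11896 CPM in IgG cells (SD, n = 6). Cxcr3, a chemokine receptor for inflamed tissue, was 2.23 ± 0.34 higher (adjusted p = 6.44e-04; adjusted p = 0.151 without the library block). The inhibitory receptor genes Lag3 (-3.96 ± 0.17 on the log2 scale, adjusted p = 4.91e-11) and Btla (-3.37 ± 0.15, adjusted p = 1.8e-13) were lower, as was Ptpn6, the phosphatase SHP-1 (-2.77 ± 0.13, adjusted p = 2.19e-09). All 5 had the same direction in 6 of 6 libraries, which the rule for naming them required. Slpi (ENSMUSG00000017002) lies on chromosome 2 (164354070 to 164389095, minus strand), Lag3 (ENSMUSG00000030124) on chromosome 6 (124904361 to 124911705, minus strand) and Btla (ENSMUSG00000052013) on chromosome 16 (45224315 to 45257670, plus strand).

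Genes of oxidative phosphorylation rose together in IgG cells, 20 of 25 higher and 1 lower (22 and 1 adjusted over the list alone). Examples were Ndufa1 of respiratory complex I (0.65 ± 0.05, adjusted p = 4.8e-10; adjusted p = 0.0587 without the library block) and Cycs, cytochrome c (0.52 ± 0.07, adjusted p = 7.4e-06). Proteasome genes rose in 16 of 21 cases (17 adjusted over the list alone), with the immunoproteasome subunit Psmb8 0.55 ± 0.07 higher (adjusted p = 9.23e-07). The list tests gave adjusted p = 2.58e-10 and 1.6e-07, and adjusted p = 0.116 for both with an estimated correlation. Genes for translocation into the endoplasmic reticulum rose in 13 of 20 cases (14 adjusted over the list alone; adjusted p = 5.1e-06, and adjusted p = 0.116 with an estimated correlation). Of 25 folding and unfolded-protein-response genes, 10 rose and 1 fell (10 and 3 adjusted over the list alone; adjusted p = 0.00341, and adjusted p = 0.408 with an estimated correlation). Cell cycle genes rose in 6 of 20 cases (11 adjusted over the list alone; adjusted p = 7.23e-05, and adjusted p = 0.408 with an estimated correlation). DNA replication genes rose in 3 of 20 (3 adjusted over the list alone; adjusted p = 8.87e-04, and adjusted p = 0.408 with an estimated correlation). Mki67 itself did not pass (0.40, adjusted p = 0.146).

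The NF-κB group fell, with 10 of 13 genes lower and none higher (11 lower adjusted over the list alone). Nfkb2 was lower by -1.32 ± 0.12 (adjusted p = 3.43e-07) and its partner Relb by -1.29 ± 0.13 (adjusted p = 8.27e-07). The list had adjusted p = 3.47e-08, and adjusted p = 0.0682 with an estimated correlation. Of 15 inhibitory and regulatory genes, 8 fell and 1 rose, with the same counts adjusted over the list alone. Cd200, a ligand of an inhibitory receptor of myeloid cells, was lower (-2.98 ± 0.23, adjusted p = 1.63e-07) and Siglecg, an inhibitory lectin of B cells, was higher (1.49 ± 0.15, adjusted p = 4.85e-07). Amino acid supply and ATF4-response genes fell in 12 of 19 cases and rose in 2 (the same adjusted over the list alone), with the transporter gene Slc7a5 at -0.80 ± 0.08 (adjusted p = 1.68e-07). The latter lists had adjusted p = 0.00388 and 8.52e-05, and adjusted p = 0.0724 and 0.116 with an estimated correlation.

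Homing and adhesion genes rose in 9 of 19 cases and fell in 1 (11 and 1 adjusted over the list alone). Integrin beta-2, Itgb2, was 0.61 ± 0.06 higher (adjusted p = 8.12e-08), and the list had adjusted p = 5.28e-04, and adjusted p = 0.0682 with an estimated correlation. Survival and apoptosis genes moved apart, 4 higher and 7 lower of 19, the same adjusted over the list alone (list adjusted p = 0.0519). The anti-apoptotic gene Bcl2 was lower (-2.08 ± 0.14, adjusted p = 5.37e-08) and its relative Bcl2l1 higher (1.18 ± 0.15, adjusted p = 7.48e-06). Tnfrsf17 was lower by -1.54 ± 0.14 (adjusted p = 7.85e-06) and Prdm1 by -0.65 ± 0.10 (adjusted p = 6.67e-05). Ptprc was lower by -0.22 ± 0.07 (adjusted p = 0.0136), a call lost without the day 21 (adjusted p = 0.0598), B220-negative (adjusted p = 0.0667) or experiment 4 spleen library (adjusted p = 0.0625), and without the library block (adjusted p = 0.655). Sdc1 (0.06 ± 0.07, adjusted p = 0.602), Cxcr4 (0.13, adjusted p = 0.417) and Cd74 (0.02, adjusted p = 0.810) did not pass. Tigit did not pass either (-0.12 ± 0.21, adjusted p = 0.745), and stood at 0.09 without the experiment 5 spleen library.

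Of 9963 genes tested, 1409 were higher and 1501 lower in IgG cells by edgeR's quasi-likelihood test with library as a block, from sums of 791232 to 51240645 UMIs. Without the block 332 were higher and 509 lower, and with sums thinned to the smallest one 455 and 530.

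IgA plasma cell-like cells were compared with IgM cells in the same fit. Receptors for mucosal homing had the largest rises of the named genes, with Ccr9 4.72 ± 0.39 higher on the log2 scale (adjusted p = 5.38e-06) and Ccr10 4.67 ± 0.40 higher (adjusted p = 6.66e-06). Ccr10 went from 22.6 ± 17.5 CPM in IgM cells to 479 ± 149 CPM in IgA cells (SD, n = 6). Itgb7 was 4.46 ± 0.38 higher (adjusted p = 6.66e-06). Tigit was 1.52 ± 0.21 higher (adjusted p = 2.75e-04), at 259 ± 89.4 CPM in IgA cells and 90.9 ± 45.1 CPM in IgM cells. The G protein-coupled receptor gene Gpr18 was lower by log2 -3.16 ± 0.13 (adjusted p = 2.99e-13). All of these held their direction in 6 of 6 libraries, which the naming rule required of all but Tigit. Ccr9 (ENSMUSG00000029530) lies on chromosome 9 (123678439 to 123784330, plus strand), Itgb7 (ENSMUSG00000001281) on chromosome 15 (102215995 to 102231944, minus strand), Tigit (ENSMUSG00000071552) on chromosome 16 (43648867 to 43664146, minus strand) and Gpr18 (ENSMUSG00000050350) on chromosome 14 (121911253 to 121915781, minus strand).

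Among the homing and adhesion genes 9 of 19 rose and 3 fell in IgA cells, with the same counts adjusted over the list alone. Klf2 was 3.07 ± 0.34 higher (adjusted p = 5.39e-05). Cxcr4 was lower by -1.84 ± 0.16 (adjusted p = 6.93e-08). B cell and antigen presentation genes fell in 14 of 21 cases and rose in none, again also adjusted over the list alone. Cd83, an activation marker, was lower by -2.75 ± 0.18 (adjusted p = 5.81e-11), Cd74 by -0.58 ± 0.06 (adjusted p = 3.02e-08) and Ptprc by -0.54 ± 0.07 (adjusted p = 3.05e-06; adjusted p = 0.126 without the library block). These lists had adjusted p = 0.0148 and 1.5e-07, and adjusted p = 0.222 for both with an estimated correlation. Oxidative phosphorylation genes rose in 13 of 25 cases and fell in 2 (16 and 2 adjusted over the list alone; adjusted p = 9.1e-05, and adjusted p = 0.576 with an estimated correlation).

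Of 15 inhibitory and regulatory genes 3 rose and 6 fell in IgA cells (3 and 7 adjusted over the list alone). Lag3 was lower (-2.74 ± 0.17, adjusted p = 2.2e-09) and Cd274, the ligand PD-L1, higher (0.88 ± 0.13, adjusted p = 2.86e-05; 0.54 and adjusted p = 0.0579 with thinned sums). That list as a whole did not pass (adjusted p = 0.431). Tnfrsf17 was 0.95 ± 0.14 higher (adjusted p = 2.28e-04). Sdc1 was 0.22 ± 0.07 higher (adjusted p = 0.0242). The Sdc1 call was lost without the B220-negative library (adjusted p = 0.0750), the spleen (adjusted p = 0.126) or marrow library of experiment 4 (adjusted p = 0.0661), or the marrow library of experiment 5 (adjusted p = 0.0710). Prdm1 (0.03 ± 0.10, adjusted p = 0.869; -0.01 without the experiment 5 spleen library) and Mki67 (0.07, adjusted p = 0.871; -0.08 without the experiment 4 marrow library) did not pass.

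The share of cells with a Tigit UMI was higher among IgA than IgM plasma cell-like cells in each library. It was 61.7% and 23.6% in experiment 4 marrow, 57.4% and 29.0% in experiment 4 spleen, 51.6% and 26.2% in experiment 5 spleen, and 49.0% and 28.1% in experiment 5 marrow. At day 21 it was 51.9% and 11.9%, and in the B220-negative library 27.4% and 6.72%. With cells thinned to 2000 UMIs, leaving out between 5.34% and 19.2% of plasma cell-like cells as too shallow, the IgA shares ranged from 9.30% in the B220-negative library to 35.8% in experiment 4 marrow. The thinned IgM shares ranged from 2.77% in the B220-negative library to 15.9% in experiment 4 spleen. In mature B cell-like cells of the experiment 5 spleen library 0.693% had a Tigit UMI, at a median of 1613 UMIs against 4849 in plasma cell-like cells. In neutrophil-like cells of experiment 4 marrow the share was 0.155%, at a median of 5224 UMIs against 7370, and in those of experiment 5 marrow it was 2.67% (2 of 75 cells). In T cell-like cells of experiment 4 spleen, a type that expresses the gene, it was 17.1% (27 of 158 cells). In T cell-like cells it was 4.44% at day 21 and in experiment 4 marrow, and 7.67% in experiment 5 spleen.

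**Figure D1:**
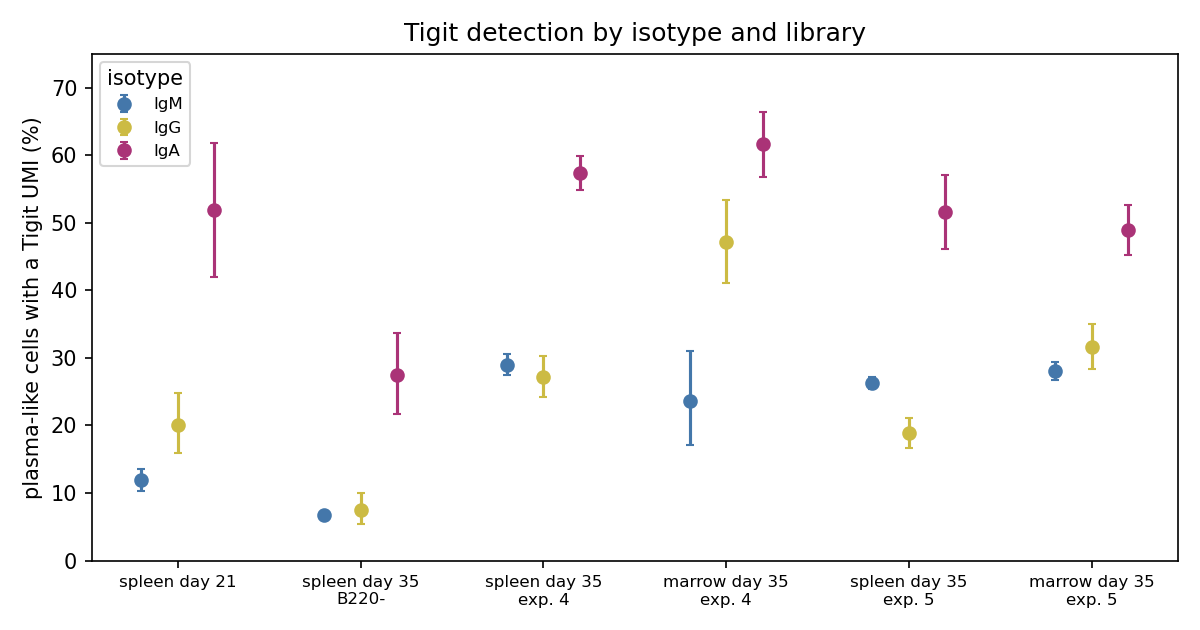
Share of plasma cell-like cells with at least 1 Tigit UMI (vertical axis, percent) for IgM, IgG and IgA cells of each of the 6 CD138+ libraries, with 95% exact binomial intervals as bars. IgA cells lie above IgM cells in every library, from 27.4% against 6.72% in the B220-negative library to 61.7% against 23.6% in experiment 4 marrow.

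In the IgA comparison edgeR called 1356 genes higher and 1493 lower of 9963 tested. Without the library block 590 were higher and 636 lower, and with thinned sums 547 and 631.

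**Figure D2:**
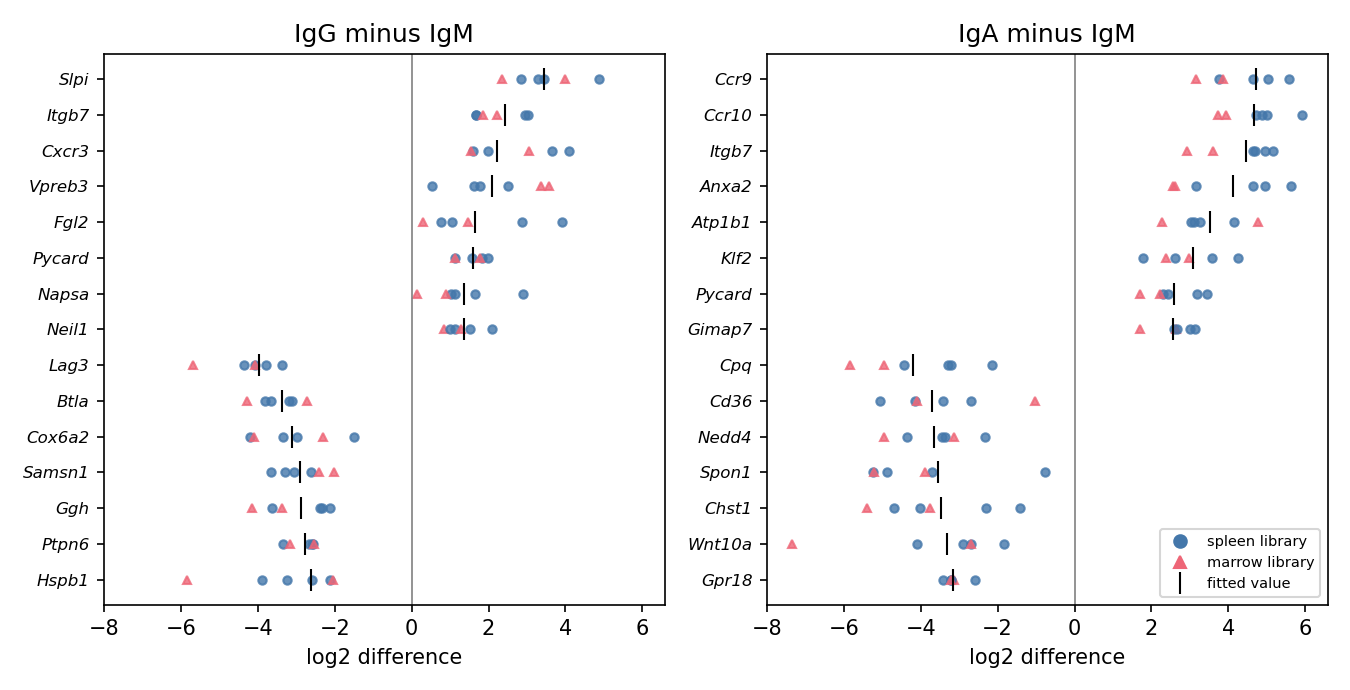
Log2 difference from IgM cells of named genes with large changes in IgG cells and in IgA cells. Each point is 1 library, circles for spleen and triangles for marrow, and the black bar is the fitted value, such as 3.45 for Slpi in IgG cells and 4.67 for Ccr10 in IgA cells.

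Whether isotype differences depended on tissue was tested as an interaction. By edgeR's quasi-likelihood test 0 of 10199 genes passed for IgG and 0 for IgA, with 386 and 496 genes at an unadjusted p under 0.05. For Tigit the IgA effect differed between marrow and spleen by -0.07 ± 0.37 on the log2 scale and the IgG effect by 0.77 ± 0.38 (adjusted p = 1 for both). For Ccr10 the IgA effect differed by -1.27 ± 0.66 (adjusted p = 1).

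Cycling plasma cell-like cells, defined by at least 4 of 20 cell cycle genes with a UMI, were compared with cells that had at most 1. Genes outside the defining set followed, such as Cdca8 of the chromosomal passenger complex, which was 6.95 ± 0.10 higher on the log2 scale (adjusted p = 8.84e-24) and went from 1.1 ± 0.27 to 133 ± 28.1 CPM (SD, n = 6). All 20 DNA replication genes rose, also adjusted over the list alone, among them the helicase subunit gene Mcm3 (4.78 ± 0.09, adjusted p = 4.43e-22). The cells were chosen on cell cycle expression, so rises of Cdca8 and of the replication list were bound to follow and are no separate support. Prg2, a proteoglycan gene that led several plasma cell-like clusters, was lower by log2 -3.11 ± 0.18 (adjusted p = 6.54e-06), from 1858 ± 853 to 229 ± 151 CPM, and Lag3 by -2.62 ± 0.27 (adjusted p = 1.49e-04). These genes moved the same way in 6 of 6 libraries, which the naming rule required of Cdca8, Prg2 and Lag3. Prg2 (ENSMUSG00000027073) lies on chromosome 2 (84980461 to 84983632, plus strand) and Cdca8 (ENSMUSG00000028873) on chromosome 4 (124918465 to 124939311, minus strand). Cells with 2 or 3 of the genes, between 4.80% and 14.9% of plasma cell-like cells per library, lay near the limit and were left out.

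Of 24 plasma cell genes, 19 fell and 2 rose in cycling cells, with the same counts adjusted over the list alone. Sdc1 was lower by -0.86 ± 0.07 (adjusted p = 6.67e-10) and Prdm1 by -0.68 ± 0.08 (adjusted p = 7.45e-08). NF-κB genes fell in 12 of 13 cases and interferon-response genes in 12 of 16, with 1 interferon gene higher, all also adjusted over the list alone. Nfkbia was lower by -1.25 ± 0.09 (adjusted p = 3.85e-10). Glycolysis genes rose in 10 of 15 cases and fell in 3, the same adjusted over the list alone, with lactate dehydrogenase Ldha 1.57 ± 0.09 higher (adjusted p = 5.64e-12). Proteasome genes rose in 18 of 21 cases and fell in 1 (19 and 1 adjusted over the list alone), such as Psma4 (0.90 ± 0.07, adjusted p = 3.55e-11). In the list tests adjusted p was 3.37e-16 for DNA replication, 3.21e-04 for plasma cell genes, 5.96e-04 for NF-κB, 0.00931 for interferon, 0.00391 for glycolysis and 4.27e-06 for the proteasome. With an estimated correlation adjusted p was 0.0875 for DNA replication, 0.397 for the proteasome and 0.347 for the other 4.

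Tnfrsf17 was lower in cycling cells by -1.07 ± 0.26 (adjusted p = 0.0145; adjusted p = 0.0622 in IgM cells alone) and Cd74 by -1.03 ± 0.14 (adjusted p = 6.45e-04), and Ptprc did not pass (-0.10, adjusted p = 0.229). Tigit did not pass (0.56 ± 0.40, adjusted p = 0.268), nor did Cxcr4 (0.13, adjusted p = 0.446). Without the B220-negative library both passed, Tigit at 0.27 (adjusted p = 0.0244) and Cxcr4 at 0.26 (adjusted p = 0.0440). Of 11117 genes edgeR called 3340 higher and 4141 lower in cycling cells, around a median over all genes of -0.11 and from sums of 1264334 to 44999659 UMIs. With sums thinned to the smallest one 2194 genes were higher and 2204 lower, and without the library block 2471 and 2736. The interaction with tissue gave 0 of 11117 genes by edgeR, with 680 at an unadjusted p under 0.05.

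The B220-negative gate and days 21 and 14 had 1 library each, from experiments 3, 1 and 2, so these differences have no replicate check. Gate, and for days 21 and 14 also day, cannot be told apart from experiment. In the B220-negative library at day 35, Rrm2, a subunit of ribonucleotide reductase, had 15.1 CPM, counted outside the immunoglobulin genes (95% exact Poisson interval 14.0 to 16.2). It had 124 (121 to 128) in experiment 4 spleen and 121 (118 to 124) in experiment 5 spleen. The median of the cell cycle list lay at log2 -3.52 against experiment 5 spleen, over 6 of its genes. Too few list genes passed the count limits against experiment 4 spleen for a median. These limits include a floor on the mean CPM of the libraries compared. Cycle genes low in the B220-negative library thus passed only if they were high in experiment 5 spleen. Tk1 of this list, at 13.5 CPM in the B220-negative library against 30.8 in experiment 5 spleen, lay below that floor. The median therefore describes these 6 genes only and may overstate the fall of the list. Tigit had 26.9 CPM (25.5 to 28.4) against 184 (180 to 189) in experiment 4 spleen and 115 (113 to 118) in experiment 5 spleen. Prg2 was higher, at 2825 CPM (2810 to 2840) against 589 (581 to 596) in experiment 4 spleen, as was Lag3, at 114 (111 to 117) against 27.4 (25.8 to 29.0). In experiment 5 spleen Prg2 had 1306 (1297 to 1314) and Lag3 39.1 (37.6 to 40.6). H2-Aa was 59.7 (57.6 to 61.9) against 199 (195 to 203) in experiment 4 spleen and 631 (625 to 637) in experiment 5 spleen, whose gate included B220+ cells. The median of the B cell list lay at -0.26 against experiment 4 (8 genes, percentile 8.67 among 10000 random lists matched on mean expression) and at -1.19 against experiment 5 spleen (9 genes, percentile 0). The median of the NF-κB list, over the 5 of its genes that passed the count limits, lay at log2 0.66 and 0.61 above the spleen libraries of experiments 4 and 5, at percentiles 99.96 and 99.88 of such random lists. Among IgG cells alone the Tigit log2 folds were -2.05 and -1.20.

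At day 21, Zfp36l2, an RNA-binding regulator of mRNA decay, had 182 CPM (175 to 189) against 26.2 (24.6 to 27.8) in experiment 4 and 37.4 (36.0 to 38.9) in experiment 5 spleen at day 35, and 29.1 (27.6 to 30.6) in the B220-negative library. Cxcr4 had 83.3 CPM (78.6 to 88.3) against 20.5 (19.2 to 21.9) and 35.6 (34.2 to 37.0), and 24.8 (23.4 to 26.2) in the B220-negative library. Isg15, an interferon-induced modifier, was lower at 46.2 (42.6 to 49.9) against 129 (125 to 132) and 141 (138 to 144). In the B220-negative library Isg15 had 50.5 (48.6 to 52.6), an interval that overlapped that of day 21. Tigit had 67.3 CPM (63.0 to 71.8), below the day 35 spleen libraries of experiments 4 and 5 and above the 26.9 of the B220-negative library. Among IgG cells alone the Tigit log2 folds at day 21 were -0.97 and -0.12. IgM cells had 53.2 CPM at day 21 against 142 and 116 in spleen of experiments 4 and 5. IgA cells had 263 CPM against 305 and 254, so they were not lower than in experiment 5. Endoplasmic reticulum folding genes had a median log2 fold of -0.30 and -0.28 against the spleen libraries of experiments 4 and 5, at percentiles 0.05 and 0.48 of random lists.

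The 13 plasma cell-like cells of the day 14 library had Mki67 at 249 CPM (170 to 351) against 124 (121 to 127) in experiment 4 spleen, 200 (197 to 204) in experiment 5 spleen and 27.7 (26.3 to 29.2) in the B220-negative library. Klf2 had 187 CPM (120 to 278) against 39.5 (37.6 to 41.4), 37.9 (36.5 to 39.4) and 9.29 (8.47 to 10.2). Tigit, with 20 UMIs, had 156 CPM (95 to 240), an interval that included the 184 of experiment 4 and the 115 of experiment 5 spleen but not the 26.9 of the B220-negative library. A log2 fold from so few cells describes those cells only, and the day 14 gate selected B220+ cells that bound NP, not CD138+ cells.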

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

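The alternatives that left out plasma cell-like clusters of low UMI counts or genes high in neutrophil-like cells were chosen after the data were seen. For the named genes 3559 values under alternatives counted as unchanged, 284 kept the direction but lost the call, 14 gained it, 38 reversed and 6 values with no test moved. A tested value counted as unchanged when it kept its direction and side of the threshold. A value with no test did so when it moved by less than the SD between the folds of the experiments, a limit that is hard to exceed. Of single-library folds 110 moved, 5 reversed and 25 stayed the same. Of the shares, 164 moved by less than their interval and 51 by more. Causes were not tested unless given. Depth limits the smallest sums most, and the changes below with thinned sums have fewer UMIs by construction.

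Marrow against spleen called 108 genes higher and 71 lower. DESeq2 called 22 and 8, immunoglobulin genes kept gave 55 and 25, thinned sums 36 and 20, low-UMI clusters left out 69 and 38, IgG cells alone 36 and 18, and IgA cells alone 10 and 7. Without the replicate block edgeR called 0 higher and 0 lower (216 genes at an unadjusted p under 0.05), also with the B220-negative library added (220). With each library left out in turn and no experiment term, so that a lone library was assumed to vary like the others, 0 to 3 genes were higher and 0 to 1 lower. Leaving out an experiment left 1 library against 1 and fold changes with no test. For experiment 5 against 4 (781 and 730), DESeq2 called 293 and 281, immunoglobulin genes kept 467 and 472, thinned sums 493 and 453, and no tissue term 272 and 233.

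For IgG cells (1409 and 1501) thinned sums gave 455 and 530 and no library block 332 and 509. For IgA cells (1356 and 1493) thinned sums gave 547 and 631 and no block 590 and 636. For cycling cells (3340 and 4141) thinned sums gave 2194 and 2204, no block 2471 and 2736, and IgG cells alone 2070 and 2172. Thinning each cell changed the experiment 4 difference between marrow and spleen to 0.165 percentage points in cycling share and 3.96 in Tigit share. With an estimated correlation 0 gene lists were called for marrow, 0 for experiment 5, 0 for IgG, 0 for IgA and 0 for cycling cells, against 4, 3, 10, 5 and 10 with the preset one; 0, 0, 6, 2 and 2 had an unadjusted p under 0.05. Fry called 0 for marrow, 0 for experiment 5 (0 and 2 at an unadjusted p under 0.05), 10 for IgG, 10 for IgA and 16 for cycling cells.

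Fold changes of named genes reversed as follows. In the marrow comparison with the B220-negative library added and no block, Sdc1 was at -0.0005, Mki67 at 0.15 and Prg2 at -0.40. Tigit was at -0.12 in IgM cells alone. In IgA cells alone Mt2 was at -0.31, Apoe 0.0361, Lgals9 0.24, Cxcr4 0.82, Tnfrsf17 -0.0757 and Klf2 -0.56. With libraries left out in turn and no experiment term, marrow values ranged from -2.54 to 10.49 for Ngp, -2.42 to 10.87 for Camp, -1.82 to 0.0719 for Plac8, -0.0503 to 0.37 for Sdc1, -0.71 to 0.43 for Cxcr4, -0.58 to 0.0722 for Mki67, and -0.63 to 0.0054 for Ptprc. They ranged from -0.0164 to 0.48 for Cd74, -0.0461 to 1.30 for Slpi, -0.34 to 1.06 for Prg2, -2.37 to 0.63 for H2-DMb2 and -9.05 to 0.72 for Pax5. For IgG cells Tigit ranged from -0.27 to 0.0897, and for IgA cells Prdm1 from -0.0092 to 0.089 and Mki67 from -0.0836 to 0.25.

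In IgG cells Cd74 was at -0.0024 with no filter and -0.0025 with thinned sums, where Tigit was at 0.0282. In IgA cells Prdm1 was at -0.0155 with no filter and -0.0083 in non-cycling cells, and Mki67 at -0.0259 with the 95% isotype call, -0.0058 in non-cycling cells and -0.0024 in day 35 libraries. In cycling cells Cxcr4 was at -0.0388 with thinned sums and Ptprc at 0.0254 without low-UMI clusters. Among single libraries, Sdc1 in B220-negative cells against experiment 4 spleen was at -0.052 in non-cycling cells. In IgG cells alone Prdm1 was at -0.25 and Ptprc at -0.003 for day 21 against experiment 4 spleen, and Prdm1 at 0.052 and Tnfrsf17 at 0.14 for B220-negative cells against experiment 5 spleen.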

Other observations

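The tests of the isotype mix, of Ngp and Camp in single cells and of Cd3 in Tigit-positive cells, and the choice of patterns, were made after the results were seen. The condition on neutrophil-like cells in the Ngp and Camp test was added, and then changed from a share of cells to a share of UMIs, after values of that test were seen.

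Light chain and variable gene usage differed between isotypes and libraries. Lambda light chain cells were 16.4% of IgM plasma cell-like cells at day 21, 15.1% in the B220-negative library, 8.96% and 7.64% in spleen and marrow of experiment 4, and 7.44% and 2.91% in those of experiment 5. Among IgA cells they were 25.1% in experiment 5 marrow (exact binomial interval 22.0 to 28.4) and 4.48% in experiment 4 spleen. The heavy chain gene Ighv1-72, known from responses to NP, was used by 9.57% of IgG cells at day 21, 12.7% in the B220-negative library, 9.43% and 5.34% in spleen and marrow of experiment 4, and 2.88% and 6.02% in those of experiment 5. In IgM cells its share was 0.652% to 3.14%. Among IgG cells Ighg2b held 50.4% in the B220-negative library, Ighg2c 52.7% at day 21, Ighg1 39.0% in experiment 4 marrow and 6.47% in experiment 5 spleen, and Ighg3 28.3% in experiment 5 spleen and 1.87% in experiment 4 marrow. No test was made of these shares.

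Further list results were as follows. In marrow, no gene of the 20 DNA replication genes and none of 25 oxidative phosphorylation genes passed, also adjusted over the list alone, while the lists had adjusted p = 8.51e-04 and 0.0375, and adjusted p = 0.995 for both with an estimated correlation. In IgA cells immediate-early and stress genes rose in 2 and fell in 8 of 19 cases (2 and 10 adjusted over the list alone; adjusted p = 0.0148), and NF-κB genes fell in 4 of 13 (4 adjusted over the list alone; adjusted p = 0.0236), with adjusted p = 0.576 for both with an estimated correlation. In cycling cells oxidative phosphorylation genes rose in 21 of 25 cases and fell in 1 (21 and 2 adjusted over the list alone; adjusted p = 4.27e-06, and adjusted p = 0.397 with an estimated correlation). Translocation genes rose in 14 of 20 cases and fell in 5, the same adjusted over the list alone (adjusted p = 0.0156, and adjusted p = 0.651 with an estimated correlation). Immediate-early genes rose in 3 and fell in 13 of 19 (3 and 14 adjusted over the list alone; adjusted p = 0.00931, and adjusted p = 0.347 with an estimated correlation). As a list, isotype regulators did not pass, with 3 higher and 8 lower of 16 in IgG cells (6 and 8 adjusted over the list alone; adjusted p = 0.0998) and 5 and 8 of 16 in IgA cells, the same adjusted over the list alone (adjusted p = 0.97).

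For several lists median, mean and test differed in sign. In IgG cells plasma cell identity had a median of -0.016, a mean of 0.067 and a test direction down, B cell genes 0.023, -0.316 and down, interferon genes -0.252, -0.182 and up, and isotype regulators -0.221, 0.052 and down. In IgA cells isotype regulators had -0.26, 0.532 and up, plasma cell identity 0.039, -0.086 and up, and DNA replication -0.03, 0 and up. For cycling cells B cell genes had 0.126, 0.130 and down. In marrow immediate-early genes had 0.105, 0.125 and down, and isotype regulators -0.080, 0.025 and up. In experiment 5 plasma cell identity had -0.049, 0.061 and up, survival genes -0.022, 0.108 and up, NF-κB -0.013, 0.177 and up, and isotype regulators 0.059, -0.044 and down.

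Ngp, Camp and Lyz2, abundant in neutrophils, were higher in marrow plasma cell-like cells, whereas 261 genes high in neutrophil-like cells took 0.453% of UMIs in marrow and 0.345% in spleen in experiment 4, and 0.369% and 0.387% in experiment 5. Cells with at least 10 Ngp and Camp UMIs held 2.17% of these UMIs in plasma cell-like cells of experiment 4 marrow (2 cells) and 23.9% in experiment 5 marrow (1 cell), against 99.9% in neutrophil-like cells of either library, although only 68.5% and 50.7% of those cells reached 10; this argues against doublets as the main source of Ngp and Camp. For the other genes doublets stay open, since the 5% of cells with most UMIs of the 261 genes held 18.8% in experiment 4 marrow, which decides nothing where plasma cells express part of the set. Free RNA from neutrophils may be the source and cannot be told apart from expression over the set. Its profile correlated with that of neutrophil-like cells at Spearman 0.677 and 0.543 in plasma cell-like and T cell-like cells of experiment 4 marrow. In experiment 5 marrow the values were 0.416 and 0.316. All lay between the bounds, across genes that are not independent replicates. An Ngp or Camp UMI was held by 541 of 843 plasma cell-like cells in experiment 4 marrow and by 56 of 6399 in experiment 5 marrow. Neutrophil-like cells were 57.5% and 1.09% of those libraries. Detection of Ngp and Camp thus went with the neutrophil-like share of these marrow libraries, as free RNA predicts, but from 1 library each. Within each experiment both genes and the neutrophil-like share were also higher in marrow than in spleen. In spleen that share was 17.0% in experiment 4 and 0.308% in experiment 5. In T cell-like cells of experiment 4 and 5 marrow the 261 genes took 5.09% and 1.81% of UMIs outside the immunoglobulin genes. That was more than in plasma cell-like cells, but from 45 and 28 cells, which may express part of the set. The tissue stays open, since no biological explanation was tested.

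A different mix of isotypes in the tissues could account for the marrow difference. Over 169 genes called in all cells, the slope of the fold in IgM cells on that in all cells was 1.089. The same direction was held by 165 of them. These values argue against the mix as the whole cause over these genes as a set. No intercept was fitted, so the largest folds weigh most in the slope. IgM cells are part of all cells, and were most of them in experiment 5 (8842 of 11170 in spleen, 4451 of 6399 in marrow). These folds are therefore not independent. Of the 179 calls, 75 recurred with the same direction in IgM cells alone, 31 in IgG and 8 in IgA cells alone, from smaller sums. Single genes still went with the mix. Ccr10 was not called in IgA cells alone, nor Slpi in IgM or IgG cells alone, as given above. Apoe was at 0.04 in IgA cells alone. Tigit, not called in all cells, was at -0.12 in IgM cells alone. The tissue itself stays open as an untested explanation.

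Tigit was higher in IgA than IgM cells, with log2 values from 1.38 to 1.75 over the alternatives. With cells thinned to 1 depth the share with a Tigit UMI was higher in IgA cells in 6 of 6 libraries, which argues against depth as the cause. A Cd3 UMI was found in 0.504% of IgA cells with Tigit (9 of 1787; interval 0.231 to 0.954) and in 91.4% of T cell-like cells, which argues against doublets with T cells as the cause, although the ratio to IgA cells without Tigit (0.255%, 4 of 1566) was 1.972, between its bounds. T cell-like cells had Tigit at 26.8, 80.7, 66.6 and 44.9 CPM at day 21, in experiment 4 spleen and marrow and in experiment 5 spleen, below the 263, 305, 297 and 254 CPM of IgA cells. The isotype itself stays open as an untested biological candidate.

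Swapping the labels within libraries gave 32 splits for each of 3 contrasts, and in each only 1, the real one, gave as many genes. It called 2910 genes for IgG against 649 at most in the others, and 2849 against 471 for IgA, so chance can be excluded there with libraries taken as independent. With the libraries of an experiment swapped together, 8 splits are too few for a share under 0.05, with 1 and 130 genes at most in the others. For cycling cells the real split called 7481 against 1, but these classes were chosen on expression, so the swap was bound to lose the difference and decides nothing.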
